A study of Homo sapiens with 42 samples.

How the data were processed

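RNA was sequenced from 42 libraries in 15 groups. They came from MV4;11 and SEMK2, human leukaemia lines that both carry a fusion of MLL (KMT2A) with AF4. MV4;11 cells were treated with DMSO, MS41, MS41N or PFI-6 at 100 nM for 6 or 24 h, with 3 libraries per compound and time. SEMK2 cells were treated with DMSO or MS41, with 3 libraries each; the labels give their dose but not which time applied. MV4;11 cells carrying a control guide or either of 2 guides against ENL gave 2 libraries per guide. MV4;11 cells from mice given vehicle or MS41 gave 3 libraries each, with no dose or time in the labels. The treatment protocol writes MS47N where the sample titles write MS41N; the name of the titles is used here. Per the labels, the in vivo libraries were made with a low-input SMART-Seq kit and all others with standard Illumina protocols, from polyadenylated RNA.

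The submitters' processing notes name CASAVA 1.8, HISAT2 2.1.0 and HTSeq 0.11.3 with genome build hg38, without their settings; the strand setting used for counting is not stated. The deposited values for the MV4;11 compound, SEMK2 and guide libraries are counts per gene, all of them whole numbers. The deposited in vivo values are also whole numbers, but they are taken here to be expected counts, because the authors, per the values themselves, adjusted them by replicate number in a step the labels do not describe. In these libraries the SD across replicate numbers of the mean log2 CPM of a vehicle and MS41 pair was 0.000774 over 10382 genes. The 5 other ways of matching the libraries gave 0.03 to 0.049, and counting noise alone would give 0.0155. The deviations of both members of a pair mirrored each other, with correlations across genes of -0.996, -0.984 and -0.99. The other tables showed no such adjustment. All 58721 gene identifiers were found in GENCODE release 29 (basic set), 45 of them second copies of the pseudoautosomal genes, so gene positions are on GRCh38.

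Total counts per library, in units of 1000000, ranged from 102.3 to 156.5 in the MV4;11 compound libraries, from 155.9 to 230.6 in SEMK2, from 77.22 to 87.81 in the guide libraries and from 99.49 to 126.7, after the authors' adjustment, in vivo. The biological coefficient of variation was 4.77% over the MV4;11 compound libraries with 16 residual degrees of freedom, 11% over SEMK2 with 4, 9.21% over the guides with 3 and 13% in vivo with 2. Within each group no library was a copy of another. Libraries of different groups were not compared in this way. The labels do not say whether replicates are separate cultures or animals, so the p-values measure a spread between samples that may be partly technical.

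Genes with low counts were removed with the default filter of edgeR 4.0.16 (filterByExpr), leaving 22711 genes in the MV4;11 compound fit, 21433 in SEMK2, 17984 in the guide fit and 21337 in vivo. Libraries were scaled with TMM factors and each table was fitted with the robust quasi-likelihood model of edgeR. All 24 MV4;11 compound libraries shared 1 fit. The knockout comparison set the mean of both ENL guides against the control guide. Adjusted p-values are Benjamini-Hochberg values over all genes of a comparison, and a gene is called below 0.05. Values are log2 fold changes with their standard error (SE), or mean CPM, counts per 1000000 counts of the TMM-scaled library size, with SD. Intervals have a confidence level of 95%. Fits and plots used R 4.3.3, Python 3.11.15 and matplotlib 3.10.9.

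The in vivo fit has a term for replicate number. The design fixed beforehand had none; the term was added after the data were examined, because the adjustment ties the libraries by number, and the choice of that fit was settled after both counts of called genes had been seen. Without the term 523 genes were called (273 higher and 250 lower), against 7 with it. Libraries counted as paired by number where each of at least 3 pairs correlated above 0.1. By this rule the MV4;11 compound and SEMK2 libraries were not paired. The 6 pairs of the knockout comparison did not all reach 0.1. With 2 libraries per guide, however, their deviations mirror each other, so each correlation is counted 2 times. A comparison of 2 guides has 2 pairs and cannot meet the rule. The rule therefore does not decide among the guides. Guide 1 and the control guide correlated at 0.24. Correlations of same-number deviations lay between -0.03 and 0.07 in the MV4;11 compound and SEMK2 comparisons and between 0.02 and 0.24 among the guides.

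Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the 22 lists of a comparison. Each test was repeated with an estimated correlation and with fry. The lists hold MLL target genes, MYC targets, progenitor genes, myeloid maturation, MHC class II, interferon response, inflammatory NF-kB genes, immediate early genes, S phase, mitosis, p53 targets, ATF4 and unfolded protein stress genes, hypoxia targets, cholesterol synthesis, oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, partners of ENL, and markers of B lineage, T and NK, erythroid and megakaryocyte, and stromal and endothelial cells. Of 418 list tests, 185 were called with the preset correlation; 52 of these kept the call with an estimated correlation and 126 with fry. Fry tests whether the genes of a list move 1 way on balance and does not compare them with other genes. The median of a list and its test had opposite signs in 79 tests, 2 of them called (progenitor genes in PFI-6 at 24 h and in the knockout).

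Comparisons, tests, gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule names MLLT1 in every comparison and allows MLLT3, MYC, MYB, HOXA9, HOXA10, MEIS1 and other MLL targets. In the main comparisons it adds up to 7 higher and 7 lower called genes with the largest change, an average log2 CPM of at least 3 and groups that do not overlap. It also adds up to 4 called members, by smallest p, of each called list; where a list had no called member, its member with the smallest p may be named. In the other comparisons it adds up to 3 higher and 3 lower genes.

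Alternatives fixed beforehand were DESeq2 size factors (RLE) in edgeR, DESeq2 1.42.0, no filter, a filter at a CPM of 1 in every library of a group, a term for replicate number, the compared groups fitted alone, and leaving out each library. Alternatives added after seeing the data were the removal of a trend on GC content per library (lowess, span 0.3), limma on log2 CPM in vivo, and leaving out certain libraries or genes. The GC correction was added because fold changes followed GC content across genes. Spearman's rho was -0.775 for PFI-6 at 24 h, -0.485 for PFI-6 at 6 h, -0.61 for MS41N at 24 h, -0.564 in vivo and -0.419 in SEMK2, and between -0.191 and -0.101 for MS41N at 6 h, MS41 at 6 h, MS41 at 24 h and the knockout.

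The fits were tested on simulated data with known changes, 3 draws each. Genes changed by 1 on the log2 scale were recovered in 64.9% of cases for MS41 at 24 h, 68.6% in SEMK2, 69.5% in the knockout and 64.5% in vivo; at a change of 0.25 the shares were 38.7%, 29.2%, 6.91% and 8.9%. False calls made up 4.27%, 7.49%, 11.4% and 9.38% of the calls. The simulated counts were drawn independently for each library and did not carry the adjustment by replicate number. The in vivo shares therefore do not measure how the fit performs on the deposited in vivo values. With a simulated GC trend in PFI-6 at 24 h, 8358 false calls arose over 3 draws, against 15 after the trend was removed. No deposited column was left out. Results of some single genes that the naming rule selects are not reported here.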

Results

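RNA-seq counts were collected for 42 libraries of human leukaemia cells in 15 groups. The series studies MS41, a degrader of ENL. ENL is the product of MLLT1, a chromatin reader of acetylated histones on which leukaemias with MLL fusions depend. MV4;11, a myeloid leukaemia line, gave 24 libraries: DMSO, MS41, MS41N and PFI-6 at 100 nM for 6 or 24 h, 3 per group. MS41N is a compound whose role the labels do not state, and PFI-6 is an inhibitor of the YEATS domains with which ENL and AF9 read histones. SEMK2, a B-cell precursor leukaemia line, gave 3 DMSO and 3 MS41 libraries. MV4;11 cells with a control guide, ENL guide 1 or ENL guide 2 gave 2 libraries each, and MV4;11 cells from mice given vehicle or MS41 gave 3 each. Total counts, in units of 1000000, were 102.3 to 156.5 in the MV4;11 compound libraries, 155.9 to 230.6 in SEMK2, 77.22 to 87.81 in the guide libraries and 99.49 to 126.7 in vivo. Named genes are given with log2 fold changes and edgeR adjusted p-values, or with mean CPM ± SD.

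The first comparison asks what disruption of ENL does to transcription in MV4;11. MLLT1 itself (ENSG00000130382, chromosome 19, 6210379 to 6279948 on GRCh38) was at 236 ± 18.9 CPM with the control guide, 186 ± 6.4 with guide 1 and 125 ± 3 with guide 2 (n = 2 each). The fall was -0.35 for guide 1 (adjusted p = 0.012) and -0.92 for guide 2 (adjusted p = 1.8e-05), so transcript remained in both. Over both guides it was -0.63 (SE 0.06, adjusted p = 6.4e-05). HOXA10 (chromosome 7, 27170591 to 27180261) went from 41.3 ± 0.606 to 15.7 ± 0.574 CPM, a change of -1.40 (SE 0.07, adjusted p = 2.8e-07). HOXA9 changed by -0.74, its cofactor MEIS1 by -0.61, the transcription factor MEF2C by -0.54 and MYB by -0.34 (adjusted p = 0.0038). MYC was at -0.23 and was not called (adjusted p = 0.069). Among the rises were the actin-binding protein LSP1 from 3.6 ± 1.08 to 30.3 ± 1.95 CPM (3.06, adjusted p = 1.8e-05) and the phagocyte oxidase subunit CYBB from 5.84 to 39.6 CPM (2.76, adjusted p = 6e-07). With them rose the costimulatory ligand CD86 (2.44), JAML (2.17), BASP1 (2.05), the pseudogene CES1P1 (1.88), the lectin CLEC12A (1.71) and the G-CSF receptor CSF3R (0.95). The granule protease CTSG of immature myeloid cells fell by 1.04 on the log2 scale. So did the serine synthesis gene PSAT1 (-1.18, 113 ± 9.74 against 256 ± 1.06 CPM), the cystathionine synthase CBS (-1.18), the transcription factor gene PRDM8 (-1.02) and the folate enzyme ALDH1L2 (-1.02).

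By list, 21 of 36 measured myeloid maturation genes were higher and 0 lower after knockout (26 when adjusted over the list alone, median 0.57). Its camera adjusted p was 1.22e-37, and it held with an estimated correlation (adjusted p = 0.0442). No other list held. MLL targets had 15 of 25 lower and 0 higher (20 over the list alone, median -0.30, adjusted p = 4.94e-19; adjusted p = 0.0795 with an estimated correlation). ATF4 and unfolded protein stress genes had 11 of 32 lower (14 over the list alone, adjusted p = 4.94e-19; adjusted p = 0.0795 with an estimated correlation), among them the amino acid transporter chains SLC7A5 (-0.87) and SLC3A2 (-0.60) and the stress regulator XBP1 (-0.65). MHC class II genes had 9 of 13 higher (11 over the list alone, median 1.25, adjusted p = 3.98e-17; adjusted p = 0.238 with an estimated correlation), with the invariant chain CD74 at 0.88, HLA-DMA at 1.14 and HLA-DRB1 at 0.87. MYC targets had 31 of 58 lower (50 over the list alone, adjusted p = 2.2e-18; adjusted p = 0.41 with an estimated correlation), including the pseudouridine synthase PUS1 (-0.48). S phase genes had 7 of 40 lower (13 over the list alone, adjusted p = 1.63e-07; adjusted p = 0.637 with an estimated correlation), with UHRF1 at -0.45. The p53 targets had 7 of 29 higher (11 over the list alone, adjusted p = 0.000984; adjusted p = 0.154 with an estimated correlation), with the cell-cycle inhibitor CDKN1A at 0.51. Mitochondrially encoded genes had 5 of 13 higher (6 over the list alone, adjusted p = 4.3e-06; adjusted p = 0.606 with an estimated correlation). The mitochondrial share of counts was 3.19% and 3.58% with the control guide and 3.82% to 4.66% with the ENL guides. Mitosis genes had 3 of 35 lower (4 over the list alone, adjusted p = 0.000636; adjusted p = 0.713 with an estimated correlation), and oxidative phosphorylation 4 of 52 lower (4 over the list alone, adjusted p = 0.00173; adjusted p = 0.81 with an estimated correlation). Progenitor and stromal lists, both with adjusted p = 0.0403, came to adjusted p = 0.337 and 0.41 with an estimated correlation and were lost after a GC trend was removed.

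In all, 957 genes were higher and 896 lower after knockout, of 17984 tested. Guide 1 alone gave 782 and 564, guide 2 alone 572 and 316, and all 888 genes called for guide 2 had the same sign for guide 1. Both guides were compared with the same control libraries, which by itself favours the same sign. Between the guides edgeR called 0 genes, with 261 at an unadjusted p under 0.05 and 1 called by DESeq2; MLLT1 differed by -0.57 (adjusted p = 0.086). Without control replicate 2 the knockout count was 1015, and without guide 2 replicate 2 it was 940. With the GC trend removed 64.8% of the genes called in the knockout were higher, in place of 51.6%. Without control replicate 1 the knockout share was 42.4%, without control replicate 2 63.8% and without guide 2 replicate 2 66.9%. Without control replicate 1 the count was 2191 for guide 1 and 1874 for guide 2, with 43.5% and 44.7% of them higher in place of 58.1% and 64.4%. Without its own replicates 1 and 2 guide 1 gave 677 and 596, and guide 2 gave 426 and 269. The MLLT1 call of guide 1 was lost after a GC trend was removed (-0.24, adjusted p = 0.081), and the call of the MHC class II regulator CIITA (2.24, adjusted p = 0.037) was lost without either control library or either guide 1 library.

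**Figure D1:**
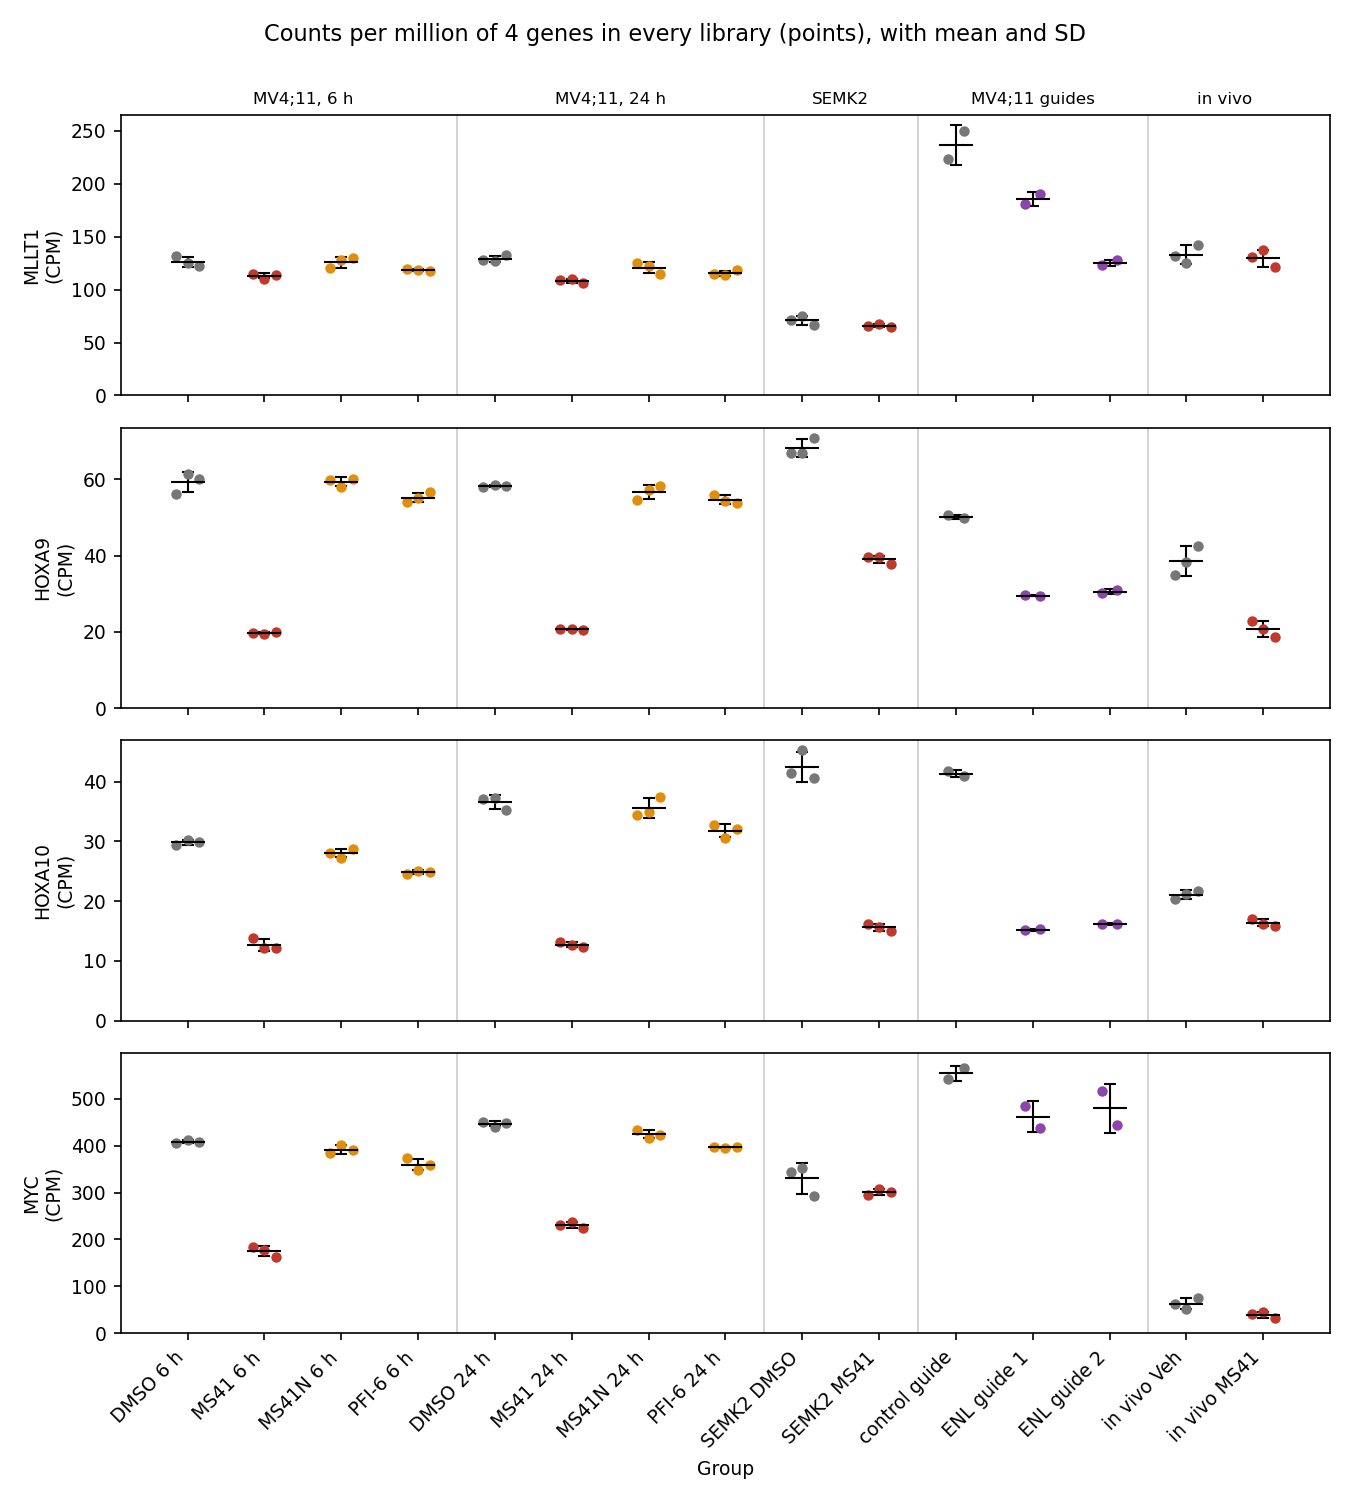
Counts per 1000000 (CPM, vertical axes starting at 0) of MLLT1, HOXA9, HOXA10 and MYC in each of the 42 libraries, by group; points are libraries, and bars show the mean and SD. HOXA9 in MV4;11 was at 19.7 CPM with MS41 and 59.3 CPM with DMSO at 6 h, and at 55.2 CPM with PFI-6 at 6 h.

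MS41 at 6 h asks which genes respond first in MV4;11. Among genes of an average log2 CPM of at least 3 with groups that did not overlap, the homeobox genes PITX1 and HOXA9 had the largest falls. PITX1 went from 233 ± 6.64 to 64.5 ± 3.41 CPM (-1.85, SE 0.06, adjusted p = 3.3e-14). HOXA9 (chromosome 7, 27162435 to 27175180) went from 59.3 ± 2.7 to 19.7 ± 0.239 CPM (-1.59, SE 0.04, adjusted p = 5e-33; n = 3). BAHCC1 (-1.47), TRGJP1 (-1.35), the cell-cycle inhibitor CDKN1B (-1.25, 61.1 against 145 CPM), HOXA10 (-1.23) and MYC (-1.23, 175 ± 11 against 409 ± 3.7 CPM, adjusted p = 3.7e-32) followed. MEIS1 (-0.89), MYB (-0.81) and SATB1 (-0.76) also fell. CYBB rose from 2.12 ± 0.307 to 6.22 ± 0.28 CPM (1.55, SE 0.08, adjusted p = 9.3e-20). So did IPCEF1 (1.44), FAM111B (1.40), the transcriptional repressor PRDM1 (1.38), the Toll-like receptor TLR1 (1.37), JAML (1.33) and the pro-apoptotic BMF (1.04). MLLT1 mRNA changed by only -0.16 (113 against 126 CPM, adjusted p = 6.5e-05), and MLLT3, which encodes AF9, rose by 0.72 (adjusted p = 0.00079).

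Of 26 measured MLL targets, 21 were lower and 3 higher at 6 h (25 adjusted over the list alone, median -0.46, camera adjusted p = 1.1e-103). MYC targets had 50 of 58 lower (56 over the list alone, median -0.27, adjusted p = 6.13e-29), with the ribosome biogenesis genes NOP16 (-0.57) and NIP7 (-0.44). Progenitor genes had 7 of 17 lower and 2 higher (9 over the list alone, median -0.02, adjusted p = 7.48e-06), with the receptor FLT3 (-0.52, 299 against 429 CPM), SOX4 (-0.57) and CDK6 (-0.35). Myeloid maturation genes had 19 of 40 higher and 5 lower (25 over the list alone, median 0.25, adjusted p = 2.56e-05), with TLR4 (0.83) and the protease CTSS (0.44). S phase genes had 34 of 40 higher (36 over the list alone, median 0.19, adjusted p = 5.33e-21), with CCNE2 (0.59), EXO1 (0.40) and CLSPN (0.35). Interferon response genes had 16 of 40 higher and 0 lower (20 over the list alone, median 0.34, adjusted p = 1.8e-06), with SAMD9L (0.94) and CMPK2 (0.82). Inflammatory NF-kB genes had 13 of 29 higher and 3 lower (17 over the list alone, median 0.34, adjusted p = 3e-04), with the chemokine CXCL8 (0.93). These 7 lists held with an estimated correlation.

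A further 6 lists did not hold at 6 h. Ribosomal proteins had 44 of 58 lower (48 over the list alone, median -0.10, adjusted p = 3.75e-08; adjusted p = 0.29 with an estimated correlation). Mitosis genes had 17 of 35 higher and 1 lower (21 over the list alone, median 0.07, adjusted p = 2.08e-05; adjusted p = 0.191 with an estimated correlation). Stress genes had 17 of 32 lower (22 over the list alone, median -0.12, adjusted p = 6.13e-05; adjusted p = 0.0785 with an estimated correlation), with XBP1 at -0.39 and the chaperone HSP90B1 at -0.24, while the cystine transporter SLC7A11 rose by 0.99. MHC class II genes had 6 of 13 higher (8 over the list alone, median 0.29, adjusted p = 0.0367; adjusted p = 0.075 with an estimated correlation). Oxidative phosphorylation had 16 of 52 lower (16 over the list alone, adjusted p = 0.00315). Immediate early genes, with DUSP6 at -0.64 and JUNB at -0.46, had 12 of 29 lower and 6 higher (20 over the list alone, adjusted p = 0.0218). Both came to adjusted p = 0.358 with an estimated correlation and were lost after a GC trend was removed. The remaining lists were not called: p53 targets (adjusted p = 0.174), hypoxia targets (0.101), cholesterol synthesis (0.423), mitochondrially encoded genes (0.558), partners of ENL (0.338) and markers of B lineage (0.149), T and NK (0.548), erythroid and megakaryocyte (0.558) and stromal and endothelial cells (0.185). In all, 2768 genes were higher and 3129 lower of 22711 tested, 356 of them by at least 2-fold. With the GC trend removed the higher share of called genes was 57.5% in place of 46.9%.

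At 24 h of MS41 the largest rises among genes of an average log2 CPM of at least 3 with groups that did not overlap began with CYBB and LSP1. CYBB (chromosome X, 37780011 to 37813461) rose from 1.57 ± 0.108 to 81.8 ± 2.76 CPM (5.71, SE 0.08, adjusted p = 5.3e-41) and LSP1 from 3.87 ± 0.206 to 55.4 ± 0.865 CPM (3.84, SE 0.06, adjusted p = 1.2e-39). JAML (3.23), CD101 (3.18), IPCEF1 (2.89), the class II antigen-presenting chain HLA-DRA (2.77, 159 against 23.3 CPM) and SEMA6B (2.75) followed, with the macrophage colony-stimulating factor receptor CSF1R at 1.83 and lysozyme, LYZ, at 0.85 (2640 against 1460 CPM). The falls at that level were led by CDK6-AS1 (-2.24), CTSG (-1.94, SE 0.03, 29 against 112 CPM, adjusted p = 4.6e-38), the neuropeptide gene GAL (-1.77), HPDL (-1.53), PLXNA1 (-1.52), HOXA10 (-1.52) and PITX1 (-1.52). HOXA9 (-1.50), MYC (-0.95, 231 against 446 CPM), MEIS1 (-0.76) and MYB (-0.59) stayed below DMSO. MLLT1 was at -0.25 (108 against 129 CPM, adjusted p = 2.5e-09) and after removal of a GC trend at -0.04 (adjusted p = 0.19); MLLT3 was at 0.84 (adjusted p = 2.6e-05).

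Myeloid maturation genes had 34 of 40 higher and 1 lower (35 adjusted over the list alone, median 1.24, camera adjusted p = 1.09e-39). MHC class II genes had 11 of 13 higher and 0 lower (11 over the list alone, median 2.43, adjusted p = 7.03e-33), with CIITA at 2.57 (55.1 against 9.24 CPM) and HLA-DRB1 at 2.02. Interferon response genes had 28 of 40 higher and 2 lower (35 over the list alone, median 0.93, adjusted p = 3.22e-09), with SAMD9L (2.59), STAT2 (1.00) and TRIM22 (0.71). MYC targets had 54 of 58 lower (56 over the list alone, median -0.57, adjusted p = 1.19e-42), with the chaperonins HSPE1 (-1.02) and HSPD1 (-0.84, 1000 against 1800 CPM). MLL targets had 19 of 26 lower and 2 higher (21 over the list alone, median -0.40, adjusted p = 9.48e-16), with CPEB2 at -0.91. Stress genes had 21 of 32 lower (24 over the list alone, median -0.36, adjusted p = 1.29e-07), with PSAT1 (-1.10, 87.4 against 188 CPM), SLC7A5 (-0.93) and ATF4 itself (-0.63), while SLC7A11 rose by 2.50. These 6 lists held with an estimated correlation.

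Another 7 lists were called at 24 h and did not hold. Oxidative phosphorylation had 44 of 52 lower (48 over the list alone, median -0.22, adjusted p = 2.36e-07; adjusted p = 0.115 with an estimated correlation), with COX5A at -0.43. S phase genes had 29 of 40 lower (31 over the list alone, median -0.15, adjusted p = 4.61e-06; adjusted p = 0.0821 with an estimated correlation), with the replicative helicase subunits MCM6 (-0.46) and MCM4 (-0.35). Cholesterol synthesis had 15 of 27 lower (19 over the list alone, adjusted p = 0.00111), with the desaturase SCD at -0.75. Progenitor genes had 9 of 17 lower and 3 higher (12 over the list alone, adjusted p = 0.00416), with FLT3 at -0.43 and the receptor KIT higher at 1.70. The p53 targets had 14 of 29 higher and 7 lower (24 over the list alone, adjusted p = 0.0473), with CCNG2 at 1.31 and BTG2 at 0.99. Stromal and endothelial markers had 4 of 9 higher (4 over the list alone, adjusted p = 0.0438), with PECAM1, also carried by monocytes, at 1.14. Each of the last 4 lists came to adjusted p = 0.0733 with an estimated correlation. Inflammatory NF-kB genes had 13 of 29 higher and 5 lower (18 over the list alone, median 0.45, adjusted p = 0.0281; adjusted p = 0.104 with an estimated correlation), with CXCL8 at 2.35. In all, 4860 genes were higher and 5190 lower, 1627 of them by at least 2-fold, and 11406 genes (50.2%) had groups that did not overlap, where chance gives 10%. With the GC trend removed 59.1% of called genes were higher, in place of 48.4%.

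The change of the MS41 effect between 6 and 24 h was tested as an interaction, which called 2713 genes higher and 3288 lower. The rise of CYBB grew by 4.16 on the log2 scale (adjusted p = 3.6e-29), that of LSP1 by 3.41 and that of HLA-DRA by 2.57. CTSG (-1.62), GAL (-1.35) and HPDL (-1.31) were lower at 24 h than at 6 h relative to DMSO. The falls of MYC and MYB were smaller at 24 h, by 0.27 (adjusted p = 8.7e-07) and 0.21. For HOXA9 the difference was 0.09 (95% interval -0.01 to 0.19) and for MLLT1 -0.09 (adjusted p = 0.13), neither called. Of S phase genes, 39 of 40 had a lower effect at 24 h than at 6 h (39 over the list alone, median -0.39, adjusted p = 9.33e-38), and the list held with an estimated correlation (adjusted p = 0.000121). Its rise at 6 h held as well, while its fall at 24 h did not (adjusted p = 0.0821 with an estimated correlation). Myeloid maturation (33 of 40 higher, 33 over the list alone), MHC class II (12 of 13 higher, 12 over the list alone), interferon response (21 of 40 higher, 23 over the list alone) and MYC targets (49 of 58 lower, 52 over the list alone) also held, with adjusted p = 3.4e-09, 1.09e-09, 0.00757 and 0.00181 with an estimated correlation. The mitochondrial share of counts was 5.86% to 7.04% with MS41 at 24 h, against 5.2% to 5.41% with DMSO, and 7.09% in MS41 replicate 2 at 6 h. Without that library and MS41 replicate 3 at 24 h, 5236 genes were called.

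**Figure D2:**
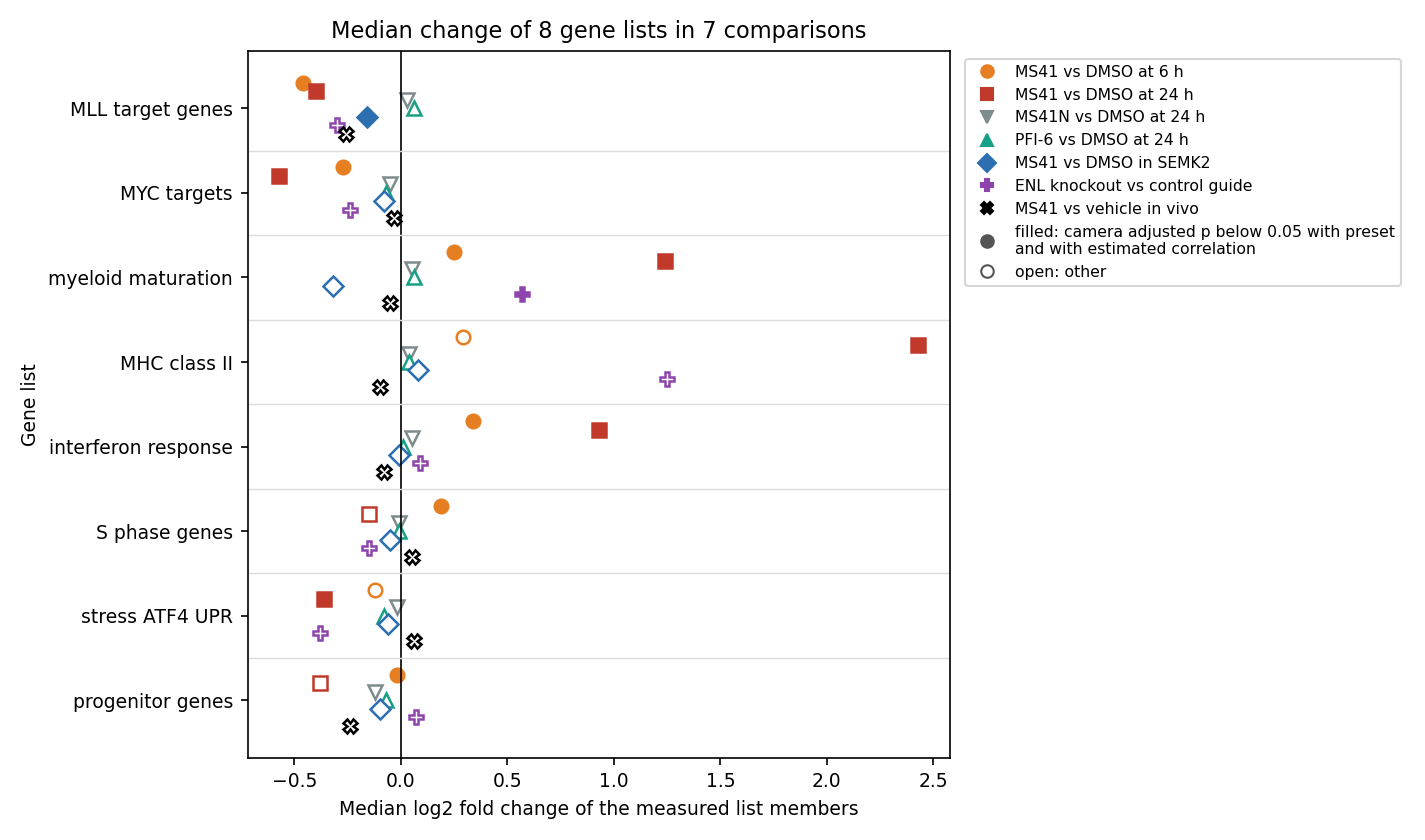
Median log2 fold change (horizontal axis) of the measured members of 8 gene lists (vertical axis) in 7 comparisons; filled points passed camera with both a preset and an estimated correlation, open points did not. MHC class II genes reached a median of 2.43 and myeloid maturation genes 1.24 with MS41 at 24 h, and MLL target genes had negative medians in the 5 comparisons of MS41 or the knockout with their controls.

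MS41N at the same dose and times changed few genes. HOXA9 was at 0.00 at 6 h (95% interval -0.07 to 0.07) and -0.04 at 24 h, MYC at -0.06 and -0.07, CYBB at 0.02 and 0.06, and MLLT1 at 0.00 and -0.10 (adjusted p = 0.99 and 0.26). At 6 h the sterol-regulated gene INSIG1 (0.15, adjusted p = 0.019) rose with the processed pseudogene RPL14P1 (0.14). The processed pseudogenes RPS10P3 (-0.44) and RPL9P28 (-0.43) and the immediate early gene NR4A2 (-0.40) fell. The call of NR4A2 was lost after a GC trend was removed (adjusted p = 0.072). At 24 h MFSD4B (0.32), ANXA1 (0.25) and TENT5A (0.20) were higher and SLC35C2 (-0.20) and the amino acid transporter chains SLC7A5 (-0.17) and SLC3A2 (-0.14) lower. Cholesterol synthesis at 6 h had 3 of 27 higher (9 over the list alone, median 0.07, camera adjusted p = 8.8e-10; adjusted p = 0.0105 with an estimated correlation), and immediate early genes 2 of 29 lower (14 over the list alone, median -0.15, adjusted p = 7.3e-12; adjusted p = 0.0397 with an estimated correlation). Of the 5 lists called at 24 h, 0 held with an estimated correlation. The counts were 6 higher and 67 lower at 6 h and 4 and 4 at 24 h. The 6 h count fell to 12 without DMSO replicate 2 and 22 without MS41N replicate 1. DESeq2 called 163 and 78, and without DMSO replicate 3 or without MS41N replicate 3 the 24 h count in edgeR was 0, with 2158 genes at an unadjusted p under 0.05 in the full comparison.

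PFI-6 gave small changes. At 24 h CYBB was at 0.44 (2.11 ± 0.142 against 1.57 ± 0.108 CPM, adjusted p = 0.0022), LSP1 at 0.36 (adjusted p = 0.00023), HLA-DRA at 0.23 (adjusted p = 0.0013), KIT at 0.27, CTSG at -0.30 (adjusted p = 1.4e-07) and HOXA10 at -0.20 (adjusted p = 0.0019). JUN (0.51) and ANXA1 (0.42) were also higher, and CCDC85B (-0.43), SLC39A4 (-0.42) and FNDC10 (-0.39) lower. At 6 h HOXA10 (-0.27, adjusted p = 0.00077), MYC (-0.18, adjusted p = 0.00029) and PITX1 (-0.26) were lower. So were the phosphatase DUSP1 (-0.48) and the processed pseudogenes RPL9P28 (-0.61) and HNRNPUP1 (-0.48), while PWAR5 (0.42), MT-TT (0.41) and STRADA (0.37) were higher. HOXA9 was at -0.10 and -0.09 and was called at neither time (adjusted p = 0.11 and 0.074), and MLLT1 was at -0.10 (adjusted p = 0.1) and -0.16 (adjusted p = 0.00038). PFI-6 called 150 genes higher and 316 lower at 6 h, and 1266 and 1540 at 24 h, of which 58 changed by at least 2-fold. The 6 h count was 126 to 309 when any 1 of its 6 libraries was left out, lowest without DMSO replicate 2, and 806 with DESeq2 and 886 with the compared groups fitted alone.

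The 24 h fold changes of PFI-6 followed GC content (rho -0.775 across 9287 genes, against -0.61 for MS41N), and with that trend removed 602 genes were called, 331 higher and 271 lower. MLLT1 then turned to 0.04 (adjusted p = 0.48), MYC (-0.17 before) went to -0.07 (adjusted p = 0.077), and CCDC85B and FNDC10 were no longer called. Of the 9 lists called at 6 h and the 7 at 24 h, 0 held with an estimated correlation. At 6 h MLL targets had 5 of 26 lower (7 over the list alone, median -0.03, adjusted p = 2.32e-05; adjusted p = 0.109 with an estimated correlation). At 24 h MYC targets had 20 of 58 lower (27 over the list alone, median -0.07, adjusted p = 4.62e-09; adjusted p = 0.291 with an estimated correlation). Without DMSO replicate 3 the 24 h count was 1381, without PFI-6 replicate 1 1869 and without PFI-6 replicate 2 1516.

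Direct tests set the compounds against each other at 100 nM. MS41 and MS41N differed in HOXA9 by -1.59 at 6 h (95% interval -1.66 to -1.52) and -1.46 at 24 h (-1.53 to -1.38), in MYC by -1.16 and -0.88, in PITX1 at 6 h by -1.76, in CYBB at 24 h by 5.65, in LSP1 by 3.65 and in CTSG by -1.79. MS41 and PFI-6 differed in HOXA9 by -1.48 (-1.56 to -1.41) and -1.40 (-1.48 to -1.33), in MYC by -1.04 and -0.78, in CYBB at 24 h by 5.28, in LSP1 by 3.48 and in CTSG by -1.65. MLL targets were lower with MS41 than with MS41N in 21 of 26 genes at 6 h (24 over the list alone, adjusted p = 7.99e-08 with an estimated correlation) and 22 at 24 h, and than with PFI-6 in 21 at either time (22 over the list alone at 6 h, adjusted p = 4.4e-08 with an estimated correlation). MS41 against MS41N called 2297 genes higher and 2657 lower at 6 h and 4647 and 4984 at 24 h. MS41 against PFI-6 called 2123 and 2299, then 4692 and 4907. MLLT1 was lower with MS41 than with MS41N by -0.16 and -0.15 (adjusted p = 5.1e-05 at 24 h; after GC removal -0.03, adjusted p = 0.26), and than with PFI-6 by -0.07 (adjusted p = 0.15) and -0.09 (adjusted p = 0.017).

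PFI-6 and MS41N differed little from each other. At 6 h 0 genes were called higher and 3 lower with PFI-6. INSIG1 (-0.17, adjusted p = 0.03) and the desaturase SCD (-0.12, adjusted p = 0.03) were among the lower ones, and both were lost with RLE factors (adjusted p = 0.07). Cholesterol synthesis was lower with PFI-6 in 3 of 27 genes (10 over the list alone, median -0.10, adjusted p = 7.38e-18; adjusted p = 0.000345 with an estimated correlation). At 24 h 10 genes were higher with PFI-6, including CD36 (0.24), ANKRD49 (0.22) and REEP3 (0.19), and 14 lower, including CD276 (-0.33), TRGV9 (-0.29) and MAD1L1 (-0.27). HOXA9 differed by -0.10 at 6 h (95% interval -0.17 to -0.04) and -0.05 at 24 h (-0.12 to 0.02), CYBB at 24 h by 0.37 (0.18 to 0.57, adjusted p = 0.12) and MLLT1 by -0.09 and -0.06, none of them called. DESeq2 called 25 and 174 genes, and the edgeR count at 24 h was 0 without MS41N replicate 1 and 4, 1 and 14 without PFI-6 replicates 1, 2 and 3. The fold changes followed GC content (rho -0.447 at 6 h and -0.697 at 24 h). With that trend removed 15 genes were called at 6 h, all 3 among them. At 24 h 11 were called, 7 of them among the 24, and 27.3% of them were higher in place of 41.7%; ANKRD49, REEP3, CD276 and MAD1L1 were no longer called.

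**Figure D3:**
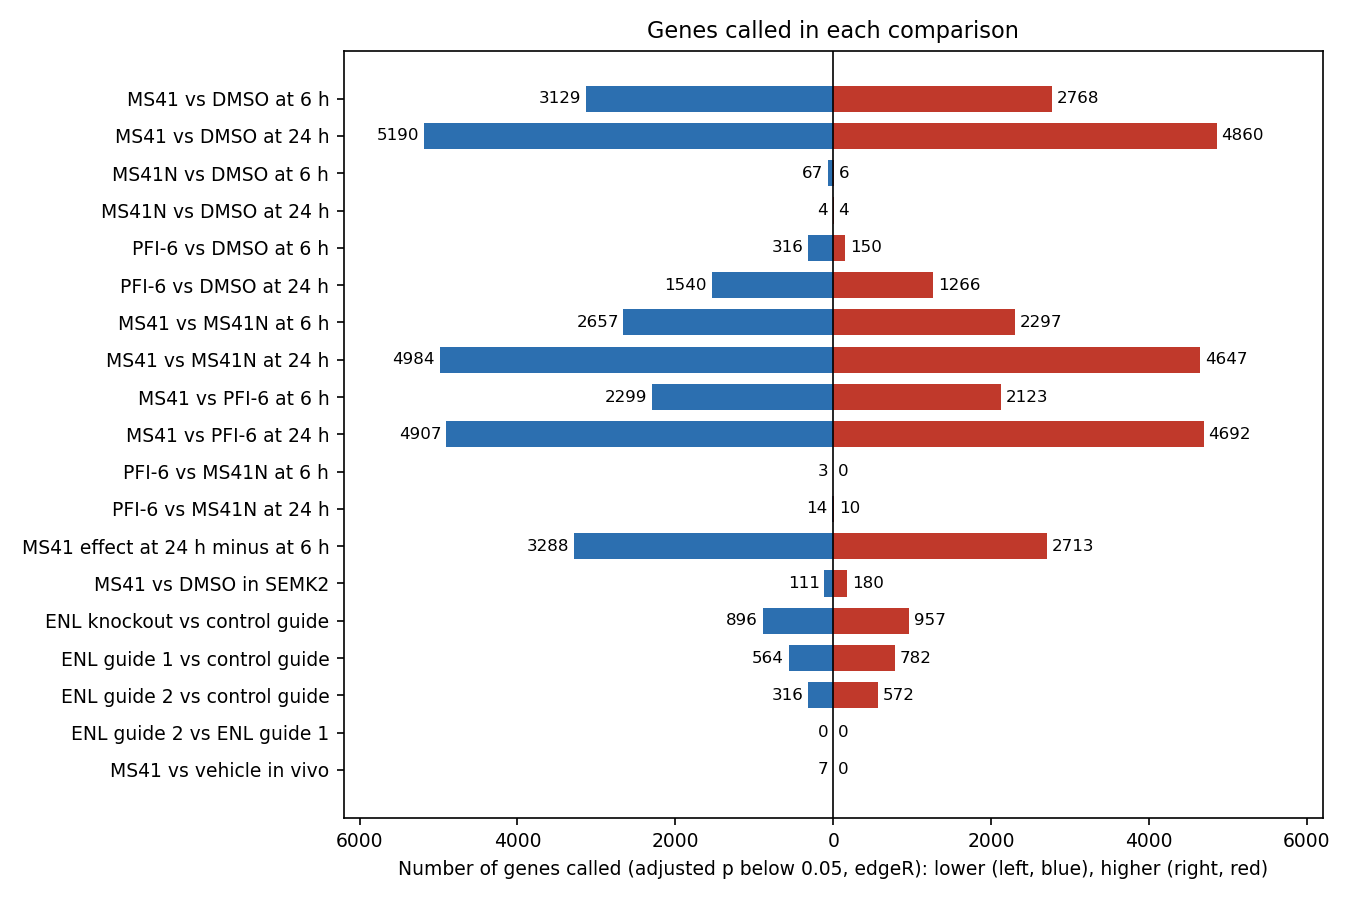
Number of genes called in each of the 19 comparisons (edgeR, adjusted p below 0.05), with genes lower to the left and genes higher to the right of 0; bars start at 0. MS41 at 24 h called 4860 genes higher and 5190 lower, MS41N at 24 h 4 and 4.

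SEMK2 asks whether MS41 acts alike in a lymphoid leukaemia with an MLL fusion. HOXA10 went from 42.4 ± 2.44 to 15.6 ± 0.613 CPM (-1.44, SE 0.06, adjusted p = 2.6e-08; n = 3). HOXA7 changed by -1.14, HOXA9 by -0.81 (39 against 68.3 CPM, adjusted p = 7e-07) and MEIS1 by -0.26 (adjusted p = 0.003). CDK6-AS1 (-1.49), ANXA2R (-1.26), ANXA2R-AS1 (-1.12), the mRNA regulator CPEB2 (-0.74) and the stem-cell surface protein PROM1 (-0.59, 440 against 664 CPM) were lower. MYC was at -0.13 (adjusted p = 0.39), MYB at -0.15 (adjusted p = 0.096) and MLLT1 at -0.11 (65.7 against 70.9 CPM, adjusted p = 0.38), none of them called. Among genes of an average log2 CPM of at least 3 the largest rise was that of REEP3, which encodes a protein of the endoplasmic reticulum, from 132 ± 6.16 to 512 ± 12.5 CPM (1.95, SE 0.04, adjusted p = 2.1e-11). The antisense gene JMJD1C-AS1 beside it (1.92) rose with the Toll-like receptor TLR10 (1.05), the lymphoid transcription factor IKZF3 (0.83), PRICKLE2 (0.77) and KLRF2 (0.74). The strand setting of the counts is not stated, so the values of JMJD1C-AS1, ANXA2R-AS1 and CDK6-AS1, which overlap a gene on the other strand, can hold reads of that gene. JMJD1C was at 406 to 456 CPM with DMSO and 379 to 396 CPM with MS41. A constant share of its reads would therefore not give the rise of JMJD1C-AS1 in SEMK2.

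MLL targets had 14 of 32 lower and 1 higher in SEMK2 (24 adjusted over the list alone, median -0.16, camera adjusted p = 3.15e-40), and this list alone held with an estimated correlation (adjusted p = 0.0395). B-lineage markers had 5 of 22 higher (11 over the list alone, median 0.07, adjusted p = 0.000168), with FCRLA at 0.61 and TCL1A at 0.29. Progenitor genes had 2 lower (3 over the list alone, adjusted p = 0.000159), PROM1 and ERG (-0.38). The p53 targets had 1 of 27 higher, BTG2 (0.62; 4 over the list alone, adjusted p = 0.00565). Stress genes had 1 lower, PSAT1 (-0.27; 6 over the list alone, adjusted p = 0.00138), and S phase genes had 0 called (3 over the list alone, adjusted p = 0.00041). The last 5 lists came to adjusted p = 0.121 each with an estimated correlation. Myeloid maturation had 1 of 30 lower, CD93 (-0.31; 3 over the list alone, median -0.32, adjusted p = 0.00488; adjusted p = 0.64 with an estimated correlation). Without DMSO replicate 1, which alone held 198 genes at least 10 times above the other SEMK2 libraries, the list's median was 0.00 (adjusted p = 0.644). MYC targets had 0 called (3 over the list alone, adjusted p = 1.04e-08; adjusted p = 0.148 with an estimated correlation), as had mitochondrially encoded genes (0 over the list alone, median 0.23, adjusted p = 1.04e-08; adjusted p = 0.385 with an estimated correlation). The mitochondrial share was 2.37%, 2.21% and 3.13% in the DMSO libraries and 2.98% to 3.23% with MS41. MHC class II had 1 of 14 higher, HLA-DRA (0.17; 1 over the list alone, adjusted p = 0.0136; adjusted p = 0.574 with an estimated correlation), and oxidative phosphorylation 1 lower, ATP5F1B (-0.15; 3 over the list alone, adjusted p = 7.26e-05; adjusted p = 0.486 with an estimated correlation).

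In SEMK2 180 genes were higher and 111 lower. DMSO replicate 3 lay apart from the other DMSO libraries, and without it 2986 genes were called, all 291 among them with the same sign. In that setting GC trend and group were confounded, with a rho of 0.597 and 0.648 in the remaining DMSO libraries and -0.494 to -0.016 with MS41. Of the 2986, 43.3% were higher, in place of 61.9% of the 291, so the majority turned to lower. With no filter 912 were called, 46.6% of them higher. The counts were 176 and 167 without DMSO replicates 1 and 2 and 130, 119 and 100 without MS41 replicates 1, 2 and 3; a removed GC trend gave 941.

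The in vivo comparison asks for the effect of MS41 on MV4;11 cells in mice. By library, rho with GC content was 0.153 to 0.62 with vehicle and -0.619 to -0.154 with MS41. GC trend and group were therefore confounded in vivo. The 7 called genes all fell, each with adjusted p = 0.015, and 1 lost its call after a GC trend was removed. They were the homeobox genes HMX2 (-1.49, SE 0.16, 6.91 ± 1.19 against 19.4 ± 3.45 CPM; n = 3), HMX3 (-0.99), HOXA9 (-0.90, SE 0.10, 20.7 ± 2.04 against 38.6 ± 3.9 CPM) and PITX1 (-0.75, 222 against 373 CPM), the lysosomal adaptor TASL (-0.68), the mRNA decay factor ZFP36L2 (-0.64, 413 against 645 CPM) and CPEB2 (-0.63, 93.5 against 145 CPM). MYC was at -0.69 (39.3 against 63.2 CPM, adjusted p = 0.38), MYB at -0.49 (adjusted p = 0.065), MEIS1 at -0.49 (adjusted p = 0.45), HOXA10 at -0.36 (adjusted p = 0.38), CYBB at 0.30 (adjusted p = 0.52), HLA-DRA at -0.13 (adjusted p = 0.87) and MLLT1 at -0.04 (95% interval -0.20 to 0.12), none of them called.

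Of 8 lists called in vivo, 0 held with an estimated correlation, and 7 kept their call after a GC trend was removed. MLL targets had 2 of 28 lower (15 adjusted over the list alone, median -0.26, camera adjusted p = 5.76e-26; adjusted p = 0.48 with an estimated correlation). Progenitor genes had 0 called (7 over the list alone, median -0.24, adjusted p = 3.44e-10; adjusted p = 0.447 with an estimated correlation), with FLT3 at -0.29 (adjusted p = 0.34). Mitosis, S phase, inflammatory NF-kB and mitochondrially encoded genes were shifted up and interferon response and ribosomal protein genes down by medians of 0.11, 0.05, 0.15, 0.06, -0.08 and -0.09; of these lists 0 members were called over all genes, while 2 NF-kB genes and 1 mitosis gene were called over the list alone. Their adjusted p was 0.584, 0.669, 0.584, 0.584, 0.732 and 0.669 with an estimated correlation. The fit had a term for replicate number, since the deposited values were adjusted by it, and without that term 523 genes were called (273 higher and 250 lower), the 7 among them. DESeq2 called 80 with the term, 38.8% of them higher, and edgeR with no filter 184, 40.8% of them higher. Without vehicle replicate 3 or MS41 replicate 3 the count in edgeR was 0, with 1623 genes at an unadjusted p under 0.05 in the full comparison. Without vehicle replicates 1 and 2 the count was 34 and 15, and without MS41 replicate 1 it was 35. The term for replicate number takes up the partner of the library left out, so each of these runs in effect drops a whole pair.

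Agreement between comparisons was measured across genes, which are not independent replicates, in 9 pairs of comparisons. MS41 at 24 h and the ENL knockout correlated with Pearson's r = 0.571 over all genes (Spearman's rho 0.59) and 0.834 over genes with an average log2 CPM of at least 3. Of 1849 genes called in the knockout, 1813 (98.1%) had the same sign with MS41 at 24 h; 888 were higher in both (244 if independent), 830 lower in both (251 if independent) and 12 opposite. These knockout genes had the same sign in 86.5% of cases with MS41 at 6 h, 74.2% and 72.1% with PFI-6 at 24 and 6 h, and 73.5% and 60.6% with MS41N. Over the genes called with MS41 at 24 h, the median ratio of the knockout change to the MS41 change was 0.435. These genes were picked by their MS41 change, which can lower the ratio. Both guides correlated with r = 0.766 (0.954 over genes of at least that level), against 0.506 in simulations of unchanged groups with shared controls.

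MS41 at 24 and 6 h correlated with r = 0.378 (0.725 at the higher level), and 5191 of the 5897 genes called at 6 h (88%) had the same sign at 24 h. MS41 at 24 h correlated with PFI-6 at r = 0.386 and with MS41N at r = 0.37, where simulated unchanged groups with shared DMSO libraries gave 0.508 and 0.502. The covariances were 0.151 and 0.136, against 0.0453 and 0.0444 in the simulations. The simulations drew each gene independently and held no trend shared by libraries, such as that on GC content. They therefore set no limit to what the shared controls contribute. SEMK2 correlated with MS41 in MV4;11 at r = 0.048 (0.417 at the higher level), with 99 genes higher in both (33 if independent), 43 lower in both (24 if independent) and 38 opposite. SEMK2 and the knockout shared 45 higher and 28 lower genes (6.82 and 4.54 if independent), with r = 0.073 (0.402 at the higher level). In vivo correlated with MS41 at 24 h at r = 0.057 (0.211 at the higher level) and with the knockout at r = 0.048 (0.135 at the higher level); 7 of the 7 in vivo genes were lower with MS41 at 24 h and 5 in the knockout.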

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

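The tests of single libraries' origin in SEMK2 DMSO replicates 1 and 3 and the splits of the samples were chosen only after the results they bear on were seen. The results listed first were singled out because an effect of MS41 differed between times, between lines or between culture and mouse; 27 named genes were examined for time, 51 for lines, and 22 gene lists for time.

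The MS41 effect in MV4;11 at 24 h differed from that at 6 h by the interaction test in 6001 genes, and S phase genes had a median difference of -0.39. Among named genes the difference was positive for CYBB (4.16), LSP1 (3.41), HLA-DRA (2.57), CD101 (2.44), SEMA6B (2.00), JAML (1.90), IPCEF1 (1.45), BMF (0.95), TLR1 (0.88), PRDM1 (0.71), PITX1 (0.33), CDKN1B (0.32), MYC (0.27), MYB (0.21) and MEIS1 (0.13). It was negative for CTSG (-1.62), GAL (-1.35), HPDL (-1.31), PLXNA1 (-1.30), CDK6-AS1 (-1.21), FAM111B (-0.35) and HOXA10 (-0.29). With labels permuted within each time, 2 of 40 splits, the real one included, called as many genes, and the highest other called 7339. Both were among the 6 splits that left a time with its groups whole, and such splits still hold the effect of MS41 at that time. The highest of the others called 0, but these put the effect of MS41 into the spread within groups. A set of splits of all 12 libraries over both times, tried after that result had been seen, gave 1 of 40 with 1990 as the highest other. Such splits put the effects of time and compound into the spread within groups, so neither set decides whether chance can be excluded.

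Between SEMK2 and MV4;11 at 24 h, all libraries of one line moved opposite to all of the other for 5 named genes, and the difference was not tested. The time of SEMK2 treatment is not given, so line and time cannot be told apart. ANXA2R was at -1.26 in SEMK2 (adjusted p = 1.9e-07) and 0.71 in MV4;11, ANXA2R-AS1 at -1.12 and 0.92, JMJD1C-AS1 at 1.92 and -0.27 (adjusted p = 0.073), PRDM1 at -0.81 (adjusted p = 0.22) and 2.09, and TASL at 0.21 (adjusted p = 0.08) and -0.86. In vivo against MV4;11 at 24 h, HLA-DRA was at -0.13 (adjusted p = 0.87) and 2.77, and IKZF3 at -1.57 (adjusted p = 0.73) and 1.79 (adjusted p = 0.021). These differences were not tested either. In vivo 30% of all genes had groups that did not overlap, with 7 of them called, so lying apart says little there.

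PFI-6 at 24 h changed genes along their GC content (rho -0.775). With the trend removed per library 602 genes were called in place of 2806, of which 384 were called in both and 379 of these had the same sign, so a GC trend of technical origin may account for most of the count. Library values of rho lay between -0.532 and -0.347 for PFI-6 at 24 h and between 0.104 and 0.418 for their DMSO libraries, so trend and group are confounded. An effect shared with the ENL knockout cannot be told apart from effects of shared DMSO libraries. After the trend was removed 78.6% of knockout genes had the same sign with PFI-6, but 71.6% had it with MS41N too, short of the margin set for the test.

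SEMK2 DMSO replicate 1 held 198 genes of at least 20 counts that stood at least 10 times above every other SEMK2 library, summing to 292 CPM, with C3 at 53.8, SPP1 at 30.7, FCGBP at 21.4, CYBB at 14.1 and STAB1 at 14 CPM; other SEMK2 libraries held 0 to 8 such genes. Reads of another library of the series are argued against for 48 of the genes (24.2%), which were over 10 times higher here than in every library outside SEMK2. In all, 94 genes (47.5%) were higher here than in every such library. For the remaining genes, among them CYBB at up to 84.5 CPM outside SEMK2, the test does not decide. RNA of microglia and of pluripotent cells is a candidate source that stays open: 16 markers, 8 of 15 in each list (C1QA, C1QB, C1QC, CX3CR1, P2RY13, TYROBP, SPP1 and FCGR3A; NANOG, SOX2, LIN28A, DPPA4, TDGF1, L1TD1, EPCAM and CDH1), were among the genes, against 1 of 15 for hepatocytes, 2 for fibroblasts, 0 for neurons and 1 for T cells. Both lists were chosen after the genes of this library had been seen, and 3 and 4 of the markers of either list were above 1 CPM in other SEMK2 libraries. With the genes left out 292 genes were called in place of 291, and the design gives no biological explanation to test.

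SEMK2 DMSO replicate 3 lay apart from DMSO replicates 1 and 2, and without it 2986 genes were called. Of 2967 of these, 2073 (69.9%) had replicate 3 at least halfway to MS41. That share and the slopes given next measure replicate 3 and MS41 from the same DMSO replicates 1 and 2. Noise in those libraries alone raises such values. The share and the slope over all genes therefore do not show how near replicate 3 lay to MS41. A treated library under the label DMSO is argued against, since over the 32 MLL targets the slope of its deviation on that of MS41 was 0.063, against 0.724 over all genes. A GC trend may be part of the cause, since its deviation had a rho of -0.762 with GC content. Each MS41 library against the other MS41 libraries gave -0.399 to 0.382. The mean of MS41 minus DMSO replicates 1 and 2 also had a rho of -0.605. By library, rho was 0.597 and 0.648 in DMSO replicates 1 and 2, -0.618 in replicate 3 and -0.494 to -0.016 with MS41. Without replicate 3, GC trend and treatment were therefore confounded. With gene length rho was 0.265 (-0.188 to 0.185 for MS41 libraries), between the limits set for the test, so a length trend cannot be told apart. With the GC trend removed 941 genes were called with replicate 3 and 1689 without it, so the trend is not the whole cause, and the design gives no biological explanation to test.

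For comparisons of 3 against 3 libraries there are 10 splits, so a share under 0.05 cannot be had. The real split alone reached its count (1 of 10) for MS41 against DMSO (5897 genes at 6 h and 10050 at 24 h), MS41N against DMSO (73 and 8), MS41 against MS41N (4954 and 9631), MS41 against PFI-6 (4422 and 9599), PFI-6 against DMSO at 6 h (466) and PFI-6 against MS41N at 24 h (24). For these the highest other split called 0 genes in edgeR. Every other split mixes libraries of both groups and so puts the difference between them into the spread within groups. A low count there does not decide whether chance can be excluded. PFI-6 at 24 h called 2806 and the highest other split 1, and SEMK2 291 and the highest other, DMSO replicates 1 and 2 with MS41 replicate 2, 84. PFI-6 against MS41N at 6 h called 3, and 2 of 10 splits called as many. The highest other, which set MS41N replicate 1 with PFI-6 replicates 2 and 3, called 38, which points to a structure of the samples. Both of these highest other splits part the libraries by their trend with GC content (rho -0.101 to -0.064 against 0.161 to 0.321 for PFI-6 and MS41N, and -0.016 to 0.648 against -0.618 to -0.294 in SEMK2). In vivo 3 of 10 splits called as many as the 7 of the real one, the highest other 30. The real split parts all 3 pairs of replicate number. The 2 others part only vehicle replicate 1 from MS41 replicate 1, so with the term for replicate number they measure MS41 in that pair and say nothing on chance. The 3 other splits that part all 3 pairs called 0 genes in edgeR. Each of them turns 1 pair around and so puts the effect of MS41 into the spread, so they say nothing on chance either.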

How the results depend on the processing

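Of the alternatives in this part, the removal of a GC trend, limma on log2 CPM and the joint settings in SEMK2 and in vivo were chosen after seeing the data. The counts for MS41 against DMSO, MS41N or PFI-6 in MV4;11 and for the change with time stayed within 1.5 times of the reported count in each alternative run. Of named gene results, RLE factors kept 408 on their side of the threshold and lost 3. DESeq2 kept 394 and gained 15, and no filter kept 394, gained 14 and lost 3. A stricter filter kept 404, gained 3 and lost 2. GC removal outside the in vivo comparison kept 367, lost 18, gained 5 and reversed 1. In vivo, where GC removal was run with the term for replicate number, 18 results were kept, 1 was lost and 1 was gained. Leaving out 1 library kept 2265 results, lost 207 and gained 10. The one reversed result was MLLT1 with PFI-6 at 24 h, -0.16 as reported and 0.04 after GC removal. The cause was not tested for the changes below, apart from the fewer or more genes and libraries that each setting itself brings. Changes of 0.25 were recovered in 38.7% of simulated cases with MS41 at 24 h, at an MV4;11 depth of at least 102.3 units of 1000000 counts. In the knockout, with 2 libraries per guide, the share was 6.91%. Neither depth nor the number of libraries was varied in the simulations.

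With no filter the counts were 182 and 83 for MS41N at 6 and 24 h, 723 for PFI-6 at 6 h, 20 and 189 for PFI-6 against MS41N, 912 in SEMK2, 2803 in the knockout, 2304 and 1835 for guides 1 and 2, 15 between the guides and 184 in vivo. The stricter filter gave 14 for MS41N at 24 h and 6 and 52 for PFI-6 against MS41N. GC removal gave 131 and 20 for MS41N, 602 for PFI-6 at 24 h, 15 and 11 for PFI-6 against MS41N, 941 in SEMK2 and 1689 there without DMSO replicate 3. DESeq2 gave 163 and 78 for MS41N, 806 for PFI-6 at 6 h, 25 and 174 for PFI-6 against MS41N, 760 in SEMK2, 1339 for guide 2, 1 between the guides and 80 in vivo. Fitting the compared groups alone gave 119 and 4 for MS41N, 886 for PFI-6 at 6 h, 1 and 162 for PFI-6 against MS41N and 2 between the guides. RLE factors gave 1 for PFI-6 against MS41N at 6 h. A replicate block gave 5 for that comparison, 662 in SEMK2 (50.3% of them higher, in place of 61.9%), 3203 in the knockout, 2578 and 1932 for guides 1 and 2 and 1 between the guides. By the rule given in the methods the numbers pair no samples in the MV4;11 compound libraries or SEMK2. Among the guides that rule cannot decide. In SEMK2 and among the guides the SD of the number means, 0.0466 and 0.0414, nevertheless reached or passed that of the other matchings (0.0362 to 0.0451 and 0.0224 to 0.0414), so a shared effect of replicate number is not excluded there. In vivo, leaving the block out gave 523. GC removal moved the share of higher genes from 8.22% to 19.8% for MS41N at 6 h, from 32.2% to 42.2% for PFI-6 at 6 h, from 48.3% to 59% for MS41 against MS41N and from 48.9% to 59.1% against PFI-6 at 24 h, from 41.7% to 27.3% for PFI-6 against MS41N at 24 h, and from 58.1% to 69% and 64.4% to 76.1% for guides 1 and 2. With an estimated correlation 52 of 185 list calls were kept. Over genes of an average log2 CPM of at least 3, MS41 at 24 h correlated at 0.725 with 6 h, 0.44 with PFI-6 and 0.416 with MS41N (0.499 and 0.506 in simulated unchanged groups with shared DMSO libraries), 0.417 with SEMK2, 0.834 with the knockout and 0.211 with in vivo, the guides at 0.954, the knockout with in vivo at 0.135 and with SEMK2 at 0.402.

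Leaving out 1 library, with a lone remaining sample assumed to vary like the other groups, gave 4915 to 5598 genes for MS41 at 6 h, 9234 to 9649 at 24 h, 4224 to 4530 and 8877 to 9197 against MS41N, 3638 to 3952 and 8834 to 9115 against PFI-6, and 5456 to 5763 for the change with time. MS41N gave 12 to 64 at 6 h (40 without DMSO replicate 1, 12 without DMSO replicate 2, 22, 46 and 33 without MS41N replicates 1, 2 and 3) and 0 to 9 at 24 h (3 and 0 without DMSO replicates 1 and 3, 1 and 0 without MS41N replicates 2 and 3). PFI-6 gave 126 to 309 at 6 h (205, 126 and 248 without DMSO replicates 1, 2 and 3, 309, 153 and 143 without PFI-6 replicates 1, 2 and 3) and 1381 to 2458 at 24 h (1381 without DMSO replicate 3, 1869 and 1516 without PFI-6 replicates 1 and 2). PFI-6 against MS41N gave 1 to 5 at 6 h (5 and 1 without MS41N replicates 1 and 2, 1 without PFI-6 replicate 3) and 0 to 18 at 24 h (0 without MS41N replicate 1, 4, 1 and 14 without PFI-6 replicates 1, 2 and 3). SEMK2 gave 100 to 2986 (176, 167 and 2986 without DMSO replicates 1, 2 and 3, 130, 119 and 100 without MS41 replicates 1, 2 and 3). The knockout gave 940 to 2621 (1015 without control replicate 2, 940 without guide 2 replicate 2), guide 1 596 to 2191 (2191 without control replicate 1, 677 and 596 without its own replicates 1 and 2), guide 2 269 to 1874 (1874 without control replicate 1, 426 and 269 without its own), and the guides against each other 0 to 3 (3 without guide 2 replicate 1). In vivo gave 0 to 35 (34, 15 and 0 without vehicle replicates 1, 2 and 3, 35 and 0 without MS41 replicates 1 and 3). Each in vivo run in effect drops a whole pair, since the term for replicate number takes up the partner of the library left out. The counts of 0 here are from edgeR, and the other tools were not run on these sets.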

Other observations

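The genes in this part were chosen after their values were seen, and no explanation was tested for them. REEP3 (chromosome 10, 63521363 to 63625123), at 1.95 in SEMK2, was at -0.04 in MV4;11 with MS41 at 6 h, 0.51 at 24 h (adjusted p = 3.6e-17), 0.50 in the knockout (adjusted p = 0.0023) and 0.00 in vivo (95% interval -0.14 to 0.14). Its neighbour JMJD1C-AS1 (63465229 to 63466563) was at 1.92 in SEMK2, -0.69 in MV4;11 at 6 h (adjusted p = 1.1e-05) and 0.45 in the knockout (adjusted p = 0.034). JMJD1C (63167221 to 63521850), on the opposite strand, with its first bases overlapping the start of REEP3, was at -0.13 in SEMK2 (adjusted p = 0.24). In MV4;11 at 6 h JMJD1C was lower too, at 164.9 to 174 CPM with MS41 against 212.1 to 213.2 CPM with DMSO. The counts of JMJD1C-AS1 can hold its reads.

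With MS41 in MV4;11 some genes were called in opposite directions at 6 and 24 h. FGL2 went from -0.41 to 0.60, ST8SIA4 from -0.47 to 0.33 and FUT4 from -0.29 to 0.39, while HSPA1A went from 0.35 to -0.43, CDC45 from 0.33 to -0.34, CHAF1B from 0.32 to -0.34 and E2F1 from 0.35 to -0.28. SLC7A11 was at 2.50 with MS41 at 24 h and at -1.48 in the knockout, where it was not called (adjusted p = 0.11). JUN was at -0.51 with MS41 at 24 h (adjusted p = 0.0043) and at 0.51 with PFI-6 (adjusted p = 0.013).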
